A study of Mus musculus with 2 samples.

How the data were processed

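Lung resident macrophages were sorted by flow cytometry 7 days after infection with 625 larvae of Nippostrongylus brasiliensis, as CD45-positive cells with high CD11c, Siglec-F and low CD11b. Per the labels' protocols, RNA was extracted on spin columns, polyadenylated RNA was selected with oligo-dT beads from about 500 ng, and libraries were made strand-specific by dUTP marking of the second strand. Selection with oligo-dT leaves out most RNA without a poly(A) tail, and sheared fragments make longer genes gather more reads, which does not affect a ratio of the same gene between libraries.

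The deposited values are a signal: read counts per gene that the authors divided by 1 size factor per library, with DESeq2 per the submitters' processing notes. The same notes name TopHat2, an aligner that follows reads across splice junctions, and the genome build GRCm38. The program that counted reads, its strand setting, the versions and the treatment of reads that match several places are not given in the sources used here. Overlapping genes on opposite strands and near-identical copies were therefore treated as uncertain. The table has 38293 genes, of which 1585 have no symbol, and 0 columns of other samples.

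Whole reads could be recovered from the values. In each library every non-zero value was a whole multiple of the smallest one, within a tolerance of 1e-06, so 100% of values came out whole. The size factors recovered in this way were 0.829 for WT and 0.847 for Axl-/-Mertk-/-. Their product is 0.702, whereas median-of-ratios factors taken from these 2 libraries alone multiply to 1, so the deposited factors were not made from these 2 libraries alone. The ratio between the 2 factors was 1.02 as deposited and 1.01 from these 2 libraries, which leaves the comparison nearly the same. Depth was 15282882 reads in WT and 15519680 in Axl-/-Mertk-/-. A gene with 0 reads allows up to 3 reads, which is 3.62 normalised reads in WT and 3.54 in Axl-/-Mertk-/-.

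The samples form 2 groups of 1 library each, taken from the genotype in the labels, and the table's columns were matched to them by the library number in the labels. With 1 library per group there are no residual degrees of freedom, so edgeR's quasi-likelihood test could not be fitted on the recovered reads. A rule of size was used in its place, fixed with the gene lists and most of the alternative settings before the data were examined. The ratio was log2 of the Axl-/-Mertk-/- value plus 10 over the WT value plus 10, and a gene counted as measured when its mean over both libraries was at least 20. On this scale the ratio of a low gene is understated. Ratios printed with an interval are without the pseudocount. Their exact 95% intervals (Clopper-Pearson) come from the recovered reads and cover counting error only. They treat each read as independent. Reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. As the count comparison, the number of measured genes whose interval excluded 1 was 2540, with 1196 above and 1344 below, which compares the libraries and not the genotypes.

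For each of 30 gene lists the median log2 ratio over measured members was placed as a percentile among 10000 random lists of the same size, matched in 20 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5, and lists with under 3 measured members got no percentile. The lists held the targeted receptors and ligands, macrophage programs, stress and growth programs, markers of other cells that a lung sort could hold, and sex-linked transcripts. Ear11, fixed by name, was not analysed here.

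Genes were named by a rule: the receptors Axl, Mertk and Tyro3 with Gas6 and Pros1, and the 12 highest and 12 lowest ratios among genes with a mean of at least 100. Unnamed or provisional genes were passed over, which left out 2 lower genes and 0 higher ones. From each list the rule took up to 4 members with the largest ratio in either direction and a mean of at least 50, for other cell types also the most abundant member, and the textbook genes of the IL-4 response and repair Retnla, Chil3, Arg1, Ear11, Mrc1, Fn1 and Igf1. Nos2, Cx3cr1, Ddx3y, Eif2s3y, Kdm5d, Uty, Gm20400, AA467197 and the genes brought in under the other observations were named after their values had been seen.

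Positions were taken from GENCODE vM21 for GRCm38, the build in the processing notes, by Ensembl identifier. Of all identifiers 95.1% were found there, and 99.2% of those of measured genes. Near-identical copies were searched with BLAST+ 2.17.0 (megablast, at least 90% identity over at least 100 bases) among the reference transcripts. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9.

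The rule was tested on simulated data, reads drawn for 11806 genes from these 2 libraries' means and depths with 198 genes altered. It recovered 95.5% of 3-fold and 100% of 4-fold differences in the right direction and 0% of 1.5-fold ones, and called 0 unaltered genes higher and 2 lower. The intervals covered the true ratio for 95.4% of genes. Of 200 random lists of 30 genes 6% stood apart, and a planted shift of 0.15 was found in 100% of lists. The simulation holds counting error only, with no differences between mice.

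Alternatives were pseudocounts of 1 and 50, no minimum mean or one of 100, rescaling to equal totals, equal upper quartiles or a median ratio of 1, fold thresholds of 1.5 and 3, and genes counted only where the interval excluded 1. Of these, lists were run with the pseudocounts, the minimum means and the median ratio of 1. For lists the mean over members, matching in 5 bins and leaving out members shared with another list were added. Leaving out genes within 20 Mb of Mertk or Axl was chosen after the data had been seen.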

Results

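Messenger RNA was sequenced from resident macrophages sorted from the lungs of mice infected with Nippostrongylus brasiliensis, a roundworm whose larvae migrate through the lung and damage it on their way to the gut. Each 8-week-old C57BL/6 mouse had received 625 third-stage larvae under the skin, and lungs were taken 7 days later. The sorted cells carried CD45, high CD11c, Siglec-F and low CD11b, the surface pattern of alveolar macrophages. There was 1 library from wild-type (WT) mice and 1 from mice lacking both Axl and Mertk (Axl-/-Mertk-/-), and the labels do not say whether a library holds the cells of 1 mouse or of several. Axl and Mertk are receptor kinases with which macrophages sense apoptotic cells, through the bridging ligands Gas6 and protein S. The comparison asks how macrophage expression during a worm infection, in which the type 2 cytokines IL-4 and IL-13 are made, differs where these receptors are missing.

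The WT library held 15282882 reads assigned to genes and the Axl-/-Mertk-/- library 15519680, spread over 18254 and 18390 genes. Chil3, which encodes the chitinase-like protein Ym1, took 6.27% of the reads in WT (exact binomial 95% interval, 6.26% to 6.28%) and 5.43% in Axl-/-Mertk-/- (5.42% to 5.44%). The 10 most abundant genes took 15.0% and 14.6%, and genes encoded in the mitochondrial genome 4.34% and 4.80%. With 1 library per genotype no difference has a replicate check, no spread between animals can be given and no p-value was computed. The intervals beside single genes and shares cover counting error only. Values are the deposited normalised read counts, in which 1 read is worth 1.21 in WT and 1.18 in Axl-/-Mertk-/-.

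The targeted genes were both lower in the library labelled Axl-/-Mertk-/-. Axl (GRCm38 chromosome 7, 25757273 to 25788705) had 24789.8 normalised reads in WT and 3851 in Axl-/-Mertk-/-, which is 15.5% of the WT value (exact 95% interval, 15.0% to 16.1%). Mertk (chromosome 2, 128698956 to 128802894) had 6484 and 2842 normalised reads, which is 43.8% (41.8% to 46.0%). The labels do not give the deleted part of either gene, and reads from the parts left in place are counted in these gene totals. The third receptor of the family, Tyro3, was close to the detection limit with 5 reads in WT and 12 in Axl-/-Mertk-/-. It also lies on chromosome 2 (119797733 to 119818104), within 20 Mb of Mertk. Of the ligands, Gas6 was at 251 and 198 normalised reads, a ratio of 0.790 (0.641 to 0.973). Pros1, which encodes protein S, was at 3892 and 3737, with a ratio of 0.960 whose interval includes 1 (0.914 to 1.01). The list of these genes (4 measured, median log2 ratio -0.76) holds both deleted genes, which fixes its place, and it is not counted among the lists that stood apart.

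Expression was otherwise much alike in the 2 libraries. Among 11795 measured genes 96.9% lay within 1.5-fold, and 41 genes were at least 2-fold higher and 32 at least 2-fold lower in Axl-/-Mertk-/-. Among the more abundant genes (mean of at least 100), 12 were at least 2-fold higher and 18 at least 2-fold lower. These counts depend on the pseudocount of 10 added before the ratio. With a pseudocount of 1 they were 91 higher and 52 lower, and with 50 they were 7 and 12. Without the genes within 20 Mb of Mertk or Axl, a setting chosen after the positions had been seen, they were 37 and 21. The counting interval of the ratio excluded 1 for 2540 genes, a comparison of these 2 libraries and not of the genotypes.

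**Figure D1:**
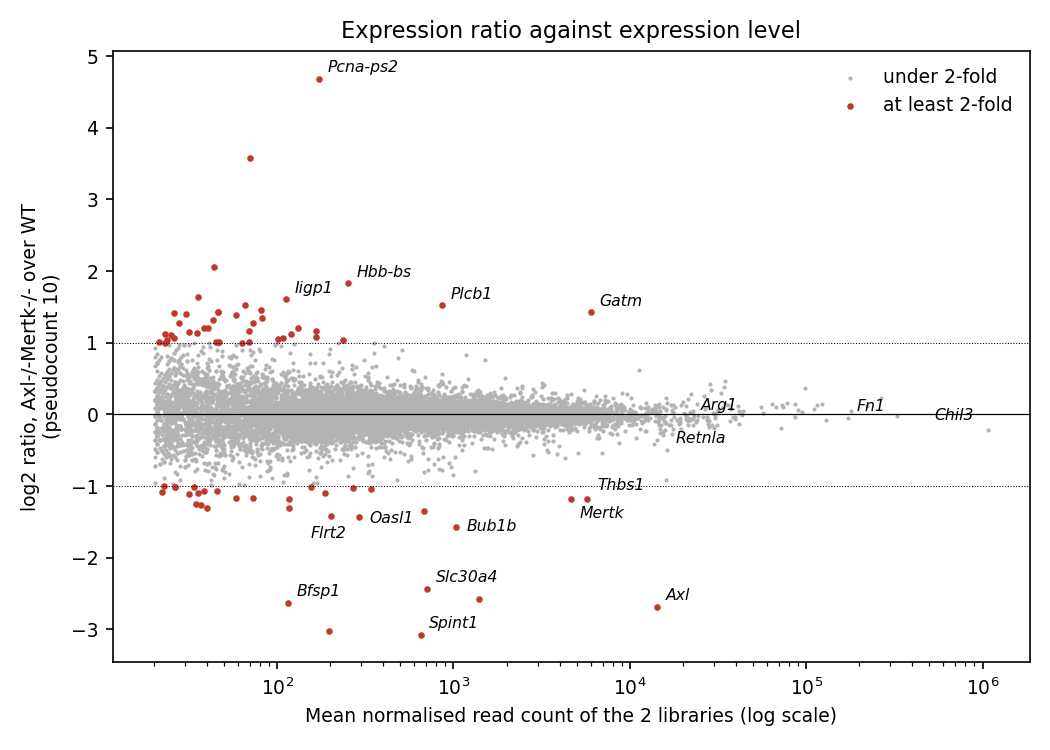
Each point is a measured gene, with its mean normalised read count over the 2 libraries on a log axis and its log2 ratio of Axl-/-Mertk-/- over WT (pseudocount 10) on the vertical axis. The 73 genes at least 2-fold different are in red, outside the dotted lines, and most abundant genes such as Chil3 and Fn1 lie near 0.

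The lowest ratios among the abundant genes came largely from chromosome 2, which carries Mertk. Spint1, a membrane inhibitor of serine proteases (chromosome 2, 119237362 to 119249527), was at 11.1% of WT (9.06% to 13.5%), with 1178 normalised reads in WT and 131.0 in Axl-/-Mertk-/-. Bfsp1, a lens filament protein (chromosome 2, 143826528 to 143863173), was at 12.1%, and the zinc transporter gene Slc30a4 (chromosome 2, 122681233 to 122702663) at 17.9%. Bub1b, a mitotic checkpoint kinase, and Ckap2l, a mitotic spindle protein, also lie within 20 Mb of Mertk and were at 33.2% and 38.7%. Thbs1, which encodes thrombospondin-1, a matrix protein that bridges apoptotic cells to phagocytes (chromosome 2, 118111876 to 118127133), was at 7931 and 3504 normalised reads, or 44.2% (42.3% to 46.1%). Other genes with low ratios lay elsewhere: Flrt2 at 35.5%, Oasl1 at 35.7%, Sel1l3 at 36.8% and Rbp4, a retinol carrier, at 40.7%. The naming rule passed over Gm20400, an antisense gene on chromosome 6 at 9.85% of WT (359.6 and 35.4 normalised reads), and AA467197 on chromosome 2 at 16.4%. Gm20400 is uncertain because the counting strand is not known.

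Among the genes with the highest ratios, Gatm and Plcb1 also lie within 20 Mb of Mertk. Gatm, the first enzyme of creatine synthesis (chromosome 2, 122594467 to 122611303), was at 3248 and 8732 normalised reads, a ratio of 2.69 (2.57 to 2.81). Plcb1, a phospholipase C (chromosome 2, 134786067 to 135475258), was at 439 and 1287, a ratio of 2.93 (2.60 to 3.31). The processed pseudogene Pcna-ps2 on chromosome 19 had 3 reads in WT and 289 in Axl-/-Mertk-/-, a ratio of 94.2 (31.9 to 459.6). Its transcript is 99.2% identical over 781 bases to that of Pcna, on chromosome 2 within 20 Mb of Mertk, so its reads are uncertain. The beta-globin gene Hbb-bs had a ratio of 3.81 (3.003 to 4.88) and Iigp1, an interferon-induced GTPase, one of 3.45 (2.43 to 4.98). The others were Ly6a (2.47), Apol7c (2.37), Ptprb (2.33), Mzt2 (2.26), Ly6c2 (2.24), Adgrf5 (2.22) and Adgre4 (2.12). Ptprb and Adgrf5 are characteristic of vascular endothelium, and Ly6c2 of monocytes.

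**Figure D2:**
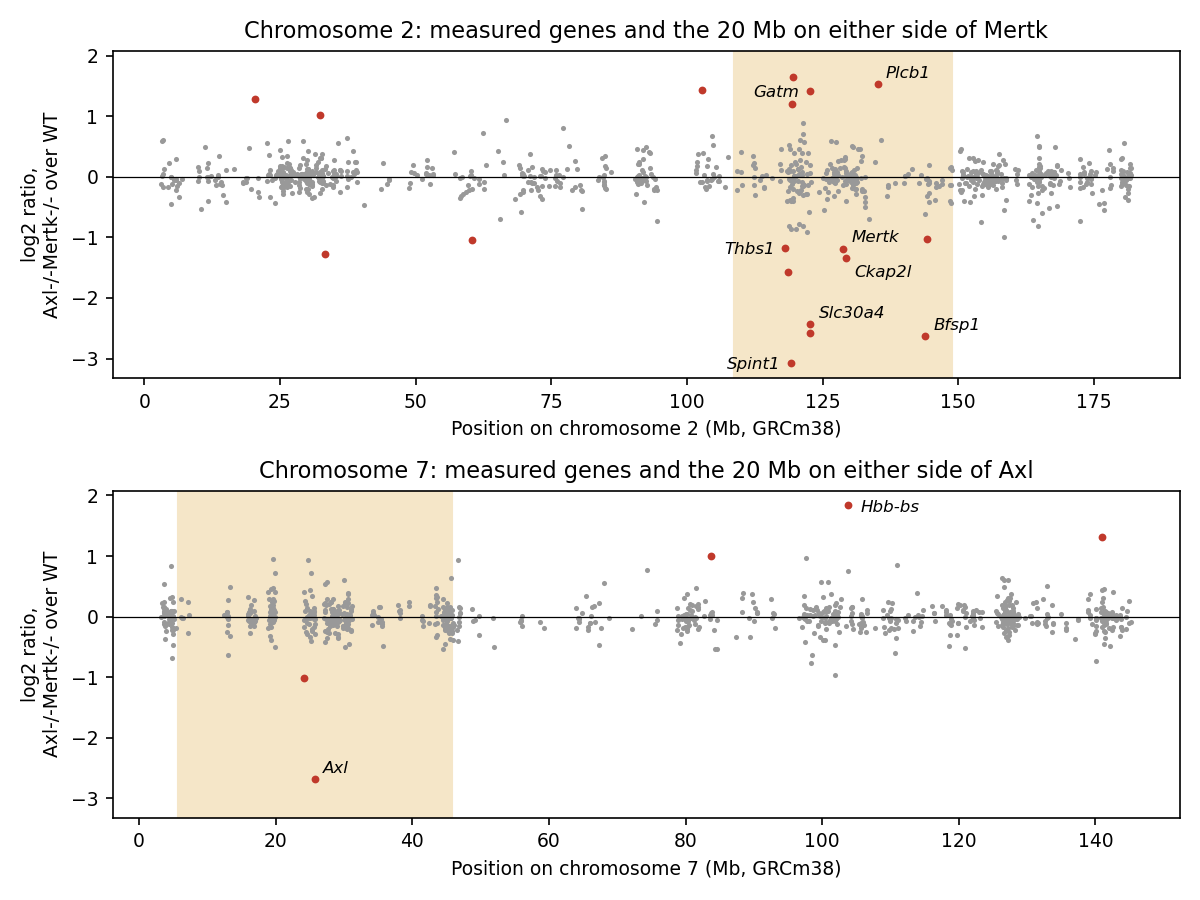
Measured genes along chromosome 2 (top) and chromosome 7 (bottom), in Mb of GRCm38, with the log2 ratio of Axl-/-Mertk-/- over WT; red marks genes at least 2-fold different and shading the 20 Mb on either side of the targeted gene. Without the targeted genes themselves, 12 red points lie in the window around Mertk and 1 in that around Axl.

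Genes of alternative activation, the program that IL-4 and IL-13 induce in macrophages, were slightly lower in Axl-/-Mertk-/-. Of 44 measured members 29 were lower and 15 higher, with a median log2 ratio of -0.08, below nearly all of 10000 random lists matched on expression (percentile 0.01). Retnla, which encodes the secreted protein RELM-alpha, was at 19051 and 13550.1 normalised reads, a ratio of 0.711 (0.694 to 0.729). Chil3 had a ratio of 0.860 (0.858 to 0.863), with reads that are uncertain because Chil4 is a near copy. Arg1, the arginine-degrading arginase 1, had a ratio of 0.885 (0.869 to 0.902), and Mrc1, the mannose receptor CD206, one of 0.914 (0.900 to 0.927). At least 1.5-fold lower was Alox15 (1213 and 724 normalised reads), which eosinophils also express. At least 1.5-fold higher were Gatm, which lies close to Mertk on the same chromosome, and Emp2 (38.6 and 107). With the mean over members in place of the median, the list lay at -0.052 and no longer stood apart (percentile 5.28). Receptors and kinases of the IL-4 pathway and other cytokine receptors were slightly higher as a group, with 20 of 27 members higher, a median log2 ratio of 0.058 and percentile 99.7. The ratio was 1.19 (1.15 to 1.24) for Tgfbr1 and 1.18 (1.07 to 1.31) for Ifnar2. It was 0.845 (0.808 to 0.885) for Il6st and 0.763 (0.623 to 0.932) for Il1rl1. These are among the other cytokine receptors, and the IL-4 pathway part of the list was not tested by itself.

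Genes of tissue repair and matrix remodelling did not stand apart as a group. Of 33 members 13 were higher and 20 lower, with a median log2 ratio of -0.04 (percentile 9.59). Fibronectin (Fn1) was among the most abundant transcripts, at 175025 and 169782 normalised reads, a ratio of 0.970 (0.963 to 0.977). The growth factor gene Igf1 had a ratio of 0.834 (0.806 to 0.864). Thbs1 and the monocyte chemokine Ccl2 (988 and 636) were at least 1.5-fold lower, and no member was 1.5-fold higher. Genes of apoptotic cell uptake lay near the centre of the random lists, with a median log2 ratio of -0.0045 over 33 members (percentile 54.5). Of these, the bridging protein gene Mfge8 had a ratio of 0.739 (0.703 to 0.776) and the integrin gene Itgb5 one of 1.22 (1.17 to 1.28). Targets of the lipid sensors PPAR and LXR (25 members, percentile 56.6), cholesterol synthesis genes (25, percentile 79.7) and lysosomal genes (35, percentile 64.5) did not stand apart either. Apoe, the apolipoprotein of cholesterol export, was at 28900.3 and 40081 normalised reads, a ratio of 1.39 (1.36 to 1.41), and the fatty acid binding protein gene Fabp4 had a ratio of 0.764 (0.718 to 0.814).

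The 2 groups of interferon genes differed in direction. Of 38 genes of the type I interferon response 30 were lower, 10 of them at least 1.5-fold, with a median log2 ratio of -0.29 (percentile 0). The pooled reads of this list, which abundant members dominate, had a ratio nearer 1, at 0.933 (0.915 to 0.951). At least 2-fold lower were Oasl1 (429.6 and 153 normalised reads), Ifit1 (259 and 116) and Ifit2 (363 and 172), which are antiviral effectors. Of 26 genes of the interferon gamma response and classical activation 20 were higher, with a median of 0.24 (percentile 100). Iigp1 (50.7 and 175), the guanylate-binding protein gene Gbp4 (80.9 and 169) and the T cell chemokine gene Cxcl9 (352 and 615) were at least 1.5-fold higher, whereas Cxcl10 (1051 and 614) and Nos2 (226 and 131) were at least 1.5-fold lower. Of 11 genes of MHC class II presentation 10 were higher, with a median of 0.28 (percentile 100). The ratio was 1.34 (1.31 to 1.36) for H2-Ab1, 1.31 (1.28 to 1.33) for H2-Aa and 1.29 (1.28 to 1.30) for the invariant chain gene Cd74. MHC class II genes are also abundant in dendritic cells, monocyte-derived macrophages and B cells, whose marker lists had medians of 0.094, 0.13 and -0.17.

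Inflammatory cytokines and NF-kB targets had a median log2 ratio of -0.04 over 40 members (percentile 5.32) and did not stand apart. The chemokine genes Ccl7 (451 and 243 normalised reads), Ccl4 (1278 and 709) and Ccl2 were at least 1.5-fold lower and no member was 1.5-fold higher. The list did stand apart with the mean over members (-0.15, percentile 0.02), and also without members within 20 Mb of Mertk or Axl (-0.093, percentile 0). Cell cycle genes were lower for 34 of 40 members, with a median of -0.22 (percentile 0), and the counting interval lay below 1 for 18 and above 1 for 0. Among them the ratio was 0.705 (0.575 to 0.864) for Kif20a, 0.757 (0.635 to 0.901) for Aurkb and 0.759 (0.638 to 0.902) for Cdk1. The member with the lowest ratio was Bub1b, on chromosome 2. Genes of the unfolded protein and amino acid stress response were lower for 20 of 23 members, with a median of -0.11 (percentile 0.03). Asns, which makes asparagine, had a ratio of 0.652 (0.502 to 0.843) and the chaperone gene Pdia4 one of 0.826 (0.798 to 0.855). Glycolysis and hypoxia genes (26 members, median -0.033, percentile 13.8) and immediate early genes, which cell dissociation can induce (34 members, median -0.0032, percentile 60.2), did not stand apart.

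Genes of alveolar macrophage identity were lower for 27 of 33 measured members, with a median log2 ratio of -0.13 (percentile 0). Ctsk, which encodes cathepsin K, had a ratio of 0.748 (0.729 to 0.768), Kcnn3 one of 0.747 (0.670 to 0.832) and Slc39a2 one of 0.725 (0.642 to 0.818). Genes of monocyte-derived and interstitial macrophages were higher for 24 of 36 members, with a median of 0.13 (percentile 100). Ly6c2 (62.8 and 140.5 normalised reads), Plac8 (144 and 296) and Cx3cr1 (229 and 394) were at least 1.5-fold higher, whereas Folr2 (226 and 111), a marker of one kind of tissue macrophage, and Thbs1 were at least 1.5-fold lower. Every comparison of gene groups in this text was thus made between libraries in which these identity markers also differed.

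Markers of cells outside the sort gate ranged from low to abundant, and several groups were higher in Axl-/-Mertk-/-. Red cell genes had a median log2 ratio of 0.99 over 7 members (percentile 100). The median was 0.49 with a pseudocount of 50, 0.45 without a minimum mean and also 0.45 with a mean of at least 100. The most abundant member, Tfrc, the transferrin receptor, was lower, at 1601 and 1257 normalised reads. The alpha-globin genes Hba-a1 (64.0 and 137 normalised reads) and Hba-a2 (38.6 and 124) are near copies and their split is uncertain. Neutrophil genes had a median of 0.36 over 13 members (percentile 100). S100a9 was at 135 and 264, whereas Ltf was lower, at 95.3 and 54.3, and the most abundant member was Trem1 at 2269 and 2451. Pooled reads had a ratio of 1.07 (1.01 to 1.15) for red cells and 1.15 (1.10 to 1.19) for neutrophils. Tfrc, which is also in the alternative activation list, gave 1327 of the 1668 pooled red cell reads in WT. In Axl-/-Mertk-/- it gave 1065 of 1833. Genes of fibroblasts, endothelium and smooth muscle had a median of 0.36 over 22 members (percentile 100), which was 0.051 (percentile 85.3) among those with a mean of at least 100. The endothelial cadherin gene Cdh5 was at 80.9 and 155 and the collagen gene Col4a1 at 107 and 201, whereas the most abundant member, Gsn, was at 4354 and 4163, and the pooled reads of this list had a ratio of 1.01 (0.978 to 1.04). Genes of T, NK and innate lymphoid cells (24 members, median 0.16, percentile 98.9) and of dendritic cells (19 members, median 0.094, percentile 97.515) stood narrowly apart. Their most abundant members were lower, Cd2 at 2335 and 1980 and Mgl2 at 4114 and 3664, and the pooled reads, which abundant members dominate, had ratios of 0.979 (0.943 to 1.02) and 0.954 (0.927 to 0.982). B and plasma cell genes were lower, with a median of -0.17 over 16 members (percentile 1.08) and a pooled ratio of 0.949 (0.911 to 0.988). These lymphoid and dendritic cell results were lost under some of the alternative settings. Eosinophil genes (8 members, median -0.14, percentile 2.54), basophil and mast cell genes (5 members, median 0.072, percentile 75.5) and lung epithelial genes (23 members, median 0.054, percentile 87.9) did not stand apart. The most abundant epithelial gene, Scgb1a1 of club cells, was at 2964 and 2432.

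**Figure D3:**
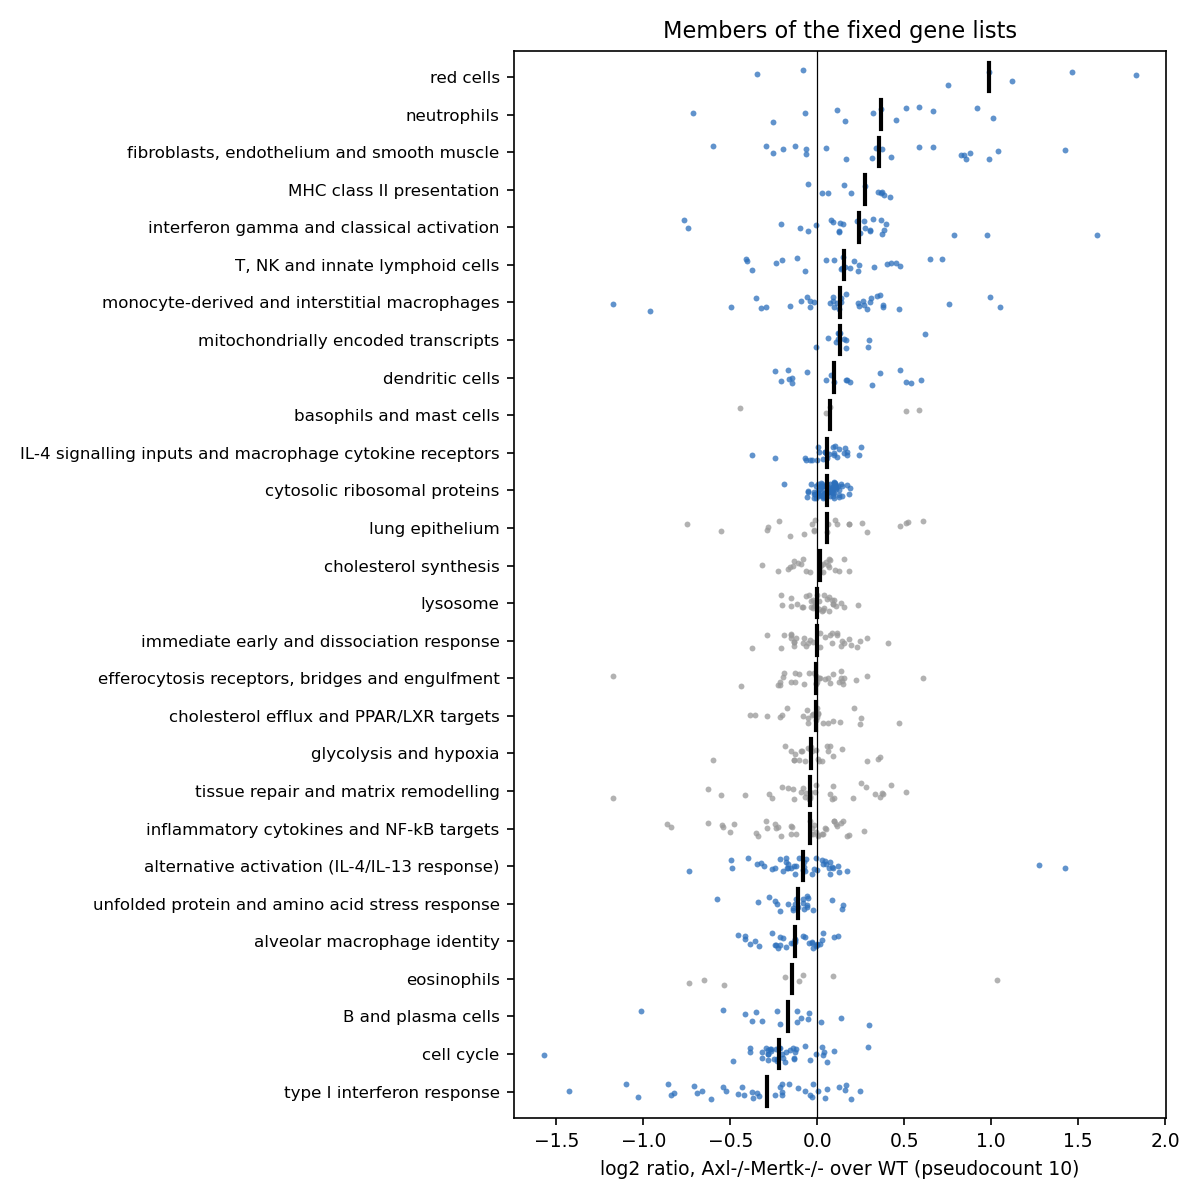
Log2 ratio of Axl-/-Mertk-/- over WT (pseudocount 10) for each measured member (points) of the gene lists, with the list median as a black bar; lists whose median stood apart from 10000 matched random lists are in blue and the others in grey. The list of the targeted receptors and their ligands and the sex-linked transcripts are left out. Medians run from -0.29 for the type I interferon response to 0.99 for red cells.

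Transcripts encoded by the mitochondrial genome were higher for 13 of 14 members, with a median log2 ratio of 0.13 (percentile 100), and the 12S ribosomal RNA gene mt-Rnr1 had a ratio of 1.53 (1.49 to 1.58). Cytosolic ribosomal protein genes were higher for 69 of 80 members, with a median of 0.058 (percentile 100). Of the sex-linked transcripts only Xist was measured, at 8697 and 9273 normalised reads. Ddx3y, Eif2s3y and Kdm5d had 0 reads in both libraries, which allows up to 3.62 normalised reads in WT and 3.54 in Axl-/-Mertk-/-. Uty had 1 read in WT and 0 in Axl-/-Mertk-/-. Without the list of the targeted receptors and ligands, 28 lists had enough members for a percentile, of which 17 stood apart, 11 higher and 6 lower, where 1.4 would be outside the bounds for random lists. Genes of one list are expressed together, so a list can stand apart between any pair of mice, and the percentiles describe these 2 libraries only.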

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

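All settings were fixed before the data were examined except that without genes within 20 Mb of Mertk or Axl. The count of genes at least 2-fold higher (41) was 91 with a pseudocount of 1, 7 with 50, 67 without a minimum mean, 12 with a mean of at least 100, 205 at 1.5-fold and 6 at 3-fold. The count lower (32) was 52, 12 and 18 with a pseudocount of 1, with 50 and with a mean of at least 100, 157 at 1.5-fold, 6 at 3-fold and 21 without genes within 20 Mb of Mertk or Axl. In the other 10 combinations of count and setting, rescalings included, the counts stayed within 1.5 times. Without the list of the targeted receptors and ligands, list medians stayed on their side of the bounds in 233 of 250 combinations; the cause of the other 17 was not tested. The sign of the median changed in 12 combinations, 0 of them for a list that stood apart: among them basophils and mast cells without a minimum mean (-0.16), lung epithelium with a mean of at least 100 (-0.019) and cholesterol synthesis with the mean over members (-0.021). The alternative activation list lost its place with the mean over members (-0.052). Dendritic cells lost theirs with a pseudocount of 1 (0.098), a mean of at least 100 (0.087), the mean over members (0.13), 5 bins (0.094) and a median ratio of 1 (0.10). B and plasma cells did so without a minimum mean (-0.11), with a mean of at least 100 (-0.11) and without the 20 Mb windows (-0.17), and T, NK and innate lymphoid cells with a mean of at least 100 (0.095) and the mean over members (0.13). Fibroblasts, endothelium and smooth muscle lost theirs with a mean of at least 100 (0.051). Eosinophils gained one with a pseudocount of 1 (-0.18), a median ratio of 1 (-0.14) and without the windows (-0.18), as did inflammatory cytokines with the mean over members (-0.15) and without the windows (-0.093). Axl and Mertk stayed within their intervals in all 8 combinations. The other named genes did so in 529 of 540, with an interval extended to the main ratio where that lay outside it. No paired analysis was possible because each group has 1 library and no test was made.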

Other observations

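The tests around Mertk and Axl, the test of read-sharing copies and both tests of a lower macrophage share were chosen after the values they rest on had been seen. The 2 tests on further marker genes were written before those genes had been looked at. Markers already seen were removed from the endothelial list after its first run, so its final form was not fixed beforehand.

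Within the list of fibroblasts, endothelium and smooth muscle, the members were divided by cell type after their values had been seen. Of the 9 measured endothelial members 8 were higher in Axl-/-Mertk-/-, 6 of them at least 1.5-fold, with a median log2 ratio of 0.66 (percentile 100). The tight junction gene Cldn5 was at 20.5 and 72.0 normalised reads and the receptor gene Kdr at 31.4 and 66.1. The most abundant of them, Vwf, was the exception, at 3339 and 3053. The 9 measured genes of fibroblasts and smooth muscle had a median of -0.064 (percentile 30.3), with Col1a1 at 149.6 and 120.4 and Col3a1 at 142 and 136, but Bgn at 48.3 and 93.3. Members of neither part, such as Col4a1 (107 and 201) and Gsn, were left out, and the difference between the 2 parts was not tested. Globin transcripts were higher alongside, Hbb-bs at 105 and 400.2 and the haem synthesis gene Alas2 at 10.9 and 35.4.

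Genes at least 2-fold different were gathered around Mertk. Within 20 Mb of it, Mertk itself left out, lay 12 such genes among 226 measured ones, 4 higher and 8 lower, while the highest number in 10000 random lists matched on expression was 9 and the highest in windows of 40 Mb on other chromosomes was 5. That argues against loss of the receptors acting on genes regardless of position as the whole source, and a candidate explanation is a chromosome segment of another mouse strain, left around the targeted gene, which may hold variants that alter expression or mapping of reads. Around Axl there was 1 such gene, Zfp235, among 326 measured ones, which leaves open whether a like segment lies there, since a segment without expressed variants would leave no trace in these counts. An effect of the targeted Mertk locus on its neighbours stays open too, and neither was tested on read sequences.

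Some near-silent genes had more reads in Axl-/-Mertk-/-. Of 6 genes with fewer than 10 reads in WT and at least 2-fold more in Axl-/-Mertk-/-, 3 had a near-identical transcript of a measured gene elsewhere, and for 2 of these the partner lay within 20 Mb of Mertk. Eif3j2 had 2 reads in WT and 117 in Axl-/-Mertk-/-, while its partner Eif3j1 (chromosome 2, 122028546 to 122056598) had 523 and 279, and Pcna-ps2 had 3 and 289 while Pcna (chromosome 2, 132249162 to 132253314) had 1542 and 1368. The third, Gm11847, had 9 and 65 reads, and its partner Hnrnpa3 (3694 and 3414 reads) lies on chromosome 2 outside that window. Variants that send reads to a copy may underlie part of these differences, but 3 genes are too few to decide. An overlapping gene pair had been left out once the first count was known. The summed reads of Pcna and its copy had a ratio of 1.05 (0.978 to 1.13). Those of Eif3j1 and its copy had one of 0.738 (0.646 to 0.842), an interval below 1. Reads moved to a copy and still counted there would not lower this sum. How reads that match several places were counted is not known, so the sum cannot decide on shared reads. For Hnrnpa3 and its copy the summed ratio was 0.919 (0.877 to 0.963), an interval that also excludes 1.

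Endothelial, red cell and monocyte genes were higher together in Axl-/-Mertk-/-. A lower share of macrophages would raise every other cell type alike only if their proportions to each other stayed the same. The highest percentile among the B cell, epithelial and eosinophil lists was 87.9. Of all 9 lists of other cell types 5 stood apart higher, 3 did not stand apart and B and plasma cells were lower. Those higher were neutrophils, dendritic cells, lymphoid cells, red cells and the mixed list of fibroblasts, endothelium and smooth muscle. The upper quartile of B and plasma cells (-0.053) lay below the lower quartile of red cells (0.33) and neutrophils (0.11). The B cell list lost its place under 3 settings. Among the lists that stood apart higher, dendritic cells, lymphoid cells and the mixed list also lost theirs under some settings. The lists thus did not move alike, which cannot decide on a lower share of macrophages. Macrophages may express abundant members of these lists, such as Cd22 (2983 and 3030 normalised reads), and Alox15 is also in the alternative activation list. Genes of alveolar macrophage identity were lower for 27 of 33 members, the direction a lower share would give. Further endothelial markers, of which 0 were in the lists above and 2 of 11 exceeded 100 normalised reads in WT, had a median log2 ratio of 0.52 (percentile 100), with Adgrl2 (1011 and 853) and Eng (532 and 663) the most abundant; 3 markers already seen had been removed from this list after its first run. Markers of patrolling monocytes had a median of 0.22 (percentile 99.99), 7 of 8 higher. The most abundant was Itgal (3902 and 4463), and the exception was Cd300ld (1230 and 1008). In WT 6 of the 8 exceeded 100 normalised reads, so macrophages may express them. Ly6c2 (62.8 and 140 normalised reads) and Plac8 (144 and 296), of the monocyte-derived list, were also higher. No list of other monocytes alone was tested, so the kind of monocyte cannot be told. More endothelial RNA and more patrolling monocytes thus both remain candidate explanations, and a lower share of macrophages stays open too. Yet a gate on CD45, high CD11c and Siglec-F should remove both endothelial cells and monocytes. A difference made by the genotype in the lung itself was not tested.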
